A study of Mus musculus with 23 samples.

How the data were processed

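Total RNA from the livers of 23 male mice was labelled with a 3' in vitro transcription kit and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per animal, per the labels' protocols. The mice fell into 4 groups by treatment and duration: 6 vehicle and 5 treated animals at 21 d, and 6 vehicle and 6 treated animals at 90 d. The submitters left out the array of 1 further treated animal of the 21 d group because of hybridisation artefacts, per the labels, and that array was not analysed here. The arrays come from separate animals, so p-values measure the spread between animals. The number of arrays limits the precision of every value.

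The deposited values are on a log2 scale with 2 decimals and run from 2.23 to 15.41. Per the submitters' processing notes, Partek and RMA (robust multi-array average) were used; their versions and settings are not given in the sources used here. The log2 base was inferred from the range of the values and from the use of RMA, and is stated by no label. Array medians were near equal, between 5.53 and 5.61. RMA is a method that corrects background, brings arrays to a common distribution and summarises probes into 1 value per probe set, so a shift common to all genes would not show in these values. No raw scans were used here, so probe signals could not be set against background.

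Of the 45101 probe sets, 64 Affymetrix control probe sets were left out and 45037 were tested. A table of the platform's annotation paired 34945 of them with 1 gene and 932 with several, and 9160 had no gene in the table used here. The Entrez identifiers of 34741 probe sets matched a RefSeq gene table of the GRCm38.p6 assembly, and no symbol changed in this step. No coordinates are given, because no build is named for the array's annotation. Each of 18193 genes was represented by the probe set with the highest mean over all 23 arrays among those paired with that gene alone. Probe sets of the same gene can differ, so calls were also made on the mean of all probe sets of a gene, and the report names the passing genes whose call ended there. Members of the Saa, Mup and Cyp families can share probes, so their values are uncertain. The probe sets are assigned to mouse genes, and whether transcripts of the human sulfotransferase transgenes bind to the mouse Sult1a1 probe set was not tested.

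The 4 group means were fitted to each probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 23 arrays sharing 1 estimate of the spread (19 residual degrees of freedom). The contrasts were treated against vehicle at 21 d, treated against vehicle at 90 d, the difference of these 2 effects, and vehicle at 90 d against vehicle at 21 d. P-values were adjusted with the Benjamini-Hochberg method over the 45037 probe sets, and a probe set passed at an adjusted p under 0.05. Fold changes are differences of mean log2 values, given with the moderated standard error (SE). Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over the 35 lists in each contrast. Camera with a correlation estimated from the data and fry were run as alternatives. Camera compares a list with all other genes, whereas fry tests the list's own genes, either for movement on balance in 1 direction or for change in either direction.

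The groups, the tests, the 35 gene lists, the rule for named genes and most other settings tried were set before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among those passing at each time, and the 8 largest each way for the difference of the effects and for the vehicle groups. It also named up to 4 passing members of each list, or the 2 members with the largest change where none passed. A further 16 genes were to be named whatever their result; 13 of these had a probe set paired with them and the others were not analysed here. The choice of tests that use the control probe sets was made after the data were seen.

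The control probe sets for Gapdh and beta-actin measure the 3' and the 5' end of the same transcript. The 3' minus 5' difference of each array was used as a measure of how far RNA or labelled product was shortened, and group means of it were compared with 2-sided exact permutation tests. The RNA quality measurements that the labels mention were not used here.

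The fit was tested on simulated data made from each probe set's mean and residual spread, with 200 changed probe sets. At 21 d, it recovered 73.1% of changes of 1.5-fold, 92.5% of 2-fold and 97.0% of 3-fold changes, with 7 false calls among the 45037 probe sets. At 90 d the shares were 77.6%, 97.0% and 100%, with 6 false calls. In simulated data for the 90 d contrast over 18193 genes, camera called a changed list and 0 of 100 random lists. The simulated genes varied independently of each other, so false list calls that come from correlation between genes were not tested. Each simulated probe set also had the same spread in all groups and no shift shared across an array. The shares recovered and the false calls thus do not cover a larger spread of treated livers or a difference in RNA integrity between groups.

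Other settings chosen at that stage were quantile normalisation, centring of each array on its median, 2 filters on dim probe sets, fits on only the groups compared, an intensity trend with a robust prior, array weights, no moderation of the variance, stricter thresholds, the replicate number as a block, other choices of a gene's probe set, and leaving out each array in turn. The settings added after the data were seen were the Gapdh 3' minus 5' difference as a covariate and a fit without the 5 arrays in which it was over 0.9. Python 3.11.15 and matplotlib 3.10.9 drew the plots.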

Results

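Gene expression was measured in the livers of male mice that carry human SULT1A1 and SULT1A2, sulfotransferases that attach sulfate to alcohols and phenols, on an FVB/N background. The mice received 1-methoxy-3-indolylmethyl alcohol (1-MIM-OH), which forms from a glucosinolate of cruciferous plants, by mouth at 26 mg/kg body mass, 3 times a week. Controls received only the vehicle, glyceryl trioctanoate. Livers were taken 24 h after the last of 10 treatments (21 d; 5 treated and 6 vehicle animals) or of 40 treatments (90 d; 6 treated and 6 vehicle animals). According to the series title, the study asked how far the expression profile resembles that caused by known genotoxic hepatocarcinogens. Each array covers 45037 probe sets for mouse transcripts, and array medians lay between 5.53 and 5.61 on the log2 scale. Within groups, the correlation between arrays was between 0.984 and 0.997.

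The control probe sets differed between treated and vehicle livers at 21 d. The 3' minus 5' difference of the Gapdh control was 1.00 ± 0.51 (SD, n = 5) in treated and 0.33 ± 0.13 (SD, n = 6) in vehicle livers at 21 d, on the log2 scale (difference 0.67, 2-sided exact permutation p = 0.0216). The beta-actin control moved the same way at 21 d (difference 0.58, exact permutation p = 0.0303). At 90 d the Gapdh value was 0.53 ± 0.40 (SD, n = 6) in treated and 0.50 ± 0.15 (SD, n = 6) in vehicle livers (difference 0.03, exact permutation p = 0.909). The difference exceeded 0.9 on 5 arrays, namely treated 21 d replicates 1, 3, 4 and 5 and treated 90 d replicate 6.

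**Figure D1:**
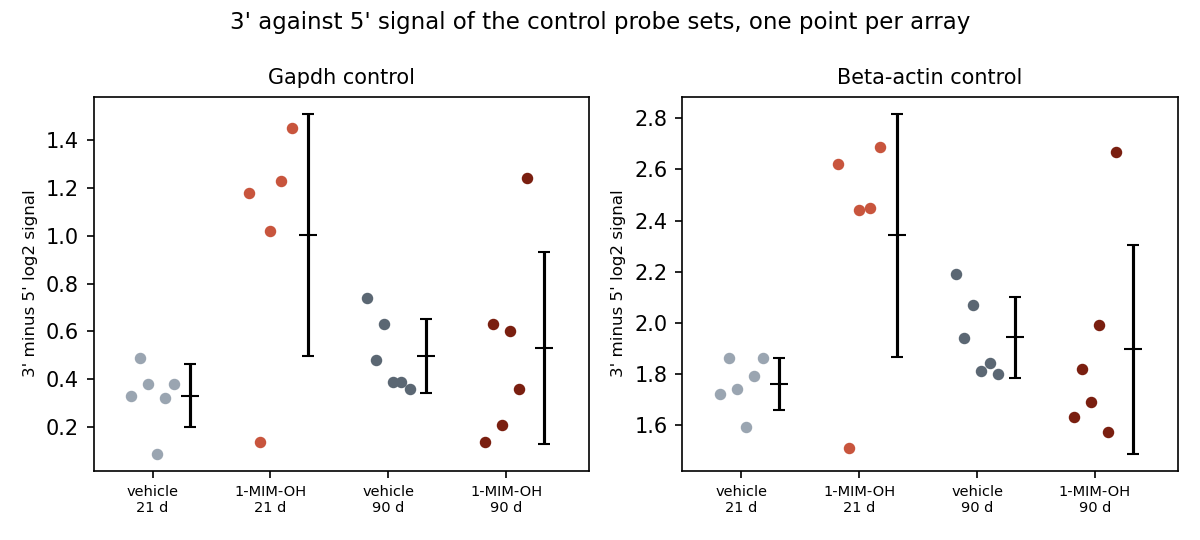
The 3' minus 5' log2 signal of the Gapdh and beta-actin control probe sets, 1 point per array, with the mean and SD of each group beside the points. For Gapdh, 4 of the 5 treated arrays at 21 d lie between 1.02 and 1.45 and replicate 2 lies at 0.14, while the vehicle arrays of both times lie between 0.09 and 0.74.

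The first comparison asked which transcripts differed after 10 treatments. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 6.06-fold, from a log2 signal of 6.83 ± 0.34 (SD, n = 6) in vehicle to 9.43 ± 0.54 (SD, n = 5) in treated livers (log2 fold change 2.60 ± 0.36 SE, limma adjusted p = 0.00135). Fhit, which encodes a dinucleoside triphosphate hydrolase and spans a common fragile site, fell from 8.98 ± 0.21 (SD, n = 6) to 6.47 ± 0.54 (SD, n = 5), with a log2 fold change of -2.51 ± 0.34 (SE, limma adjusted p = 0.0011). For both genes, all 5 treated livers lay on 1 side of all 6 vehicle livers. In total 431 probe sets passed, 183 higher and 248 lower in treated livers, which amounted to 105 higher and 108 lower genes. At an unadjusted p under 0.05 there were 7110 probe sets, against 2252 expected by chance.

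Targets of p53, the transcription factor that responds to DNA damage, rose as a group at 21 d, next to the Gapdh 3' minus 5' difference of 0.67 between the same groups. Of 33 measured members, 6 rose, 0 fell and 27 did not pass; adjusted over the list alone, 10 rose. Besides Cdkn1a, they included Phlda3, an inhibitor of Akt signalling (1.17 ± 0.20 SE on the log2 scale, limma adjusted p = 0.00829), Dglucy, a D-glutamate cyclase (0.72 ± 0.12 SE), Aen, an exonuclease that promotes apoptosis (0.57 ± 0.11 SE; 3 of its 4 probe sets had this sign), and Ccng1, cyclin G1 (0.54 ± 0.12 SE, adjusted p = 0.0385). In each of these genes the treated and vehicle livers were fully apart. The list's median log2 fold change was 0.20 (camera adjusted p = 1.31e-07; adjusted p = 0.295 with an estimated correlation). Mdm2, the ubiquitin ligase that limits p53, had a log2 fold change of 0.30 ± 0.20 (SE, adjusted p = 0.512), and Btg2, an antiproliferative gene, of 0.01 ± 0.24 (SE, adjusted p = 0.99). Btg2 had 0.71 with the Gapdh difference as a covariate (adjusted p = 0.183). It had 1.26 (adjusted p = 0.0136) without the 5 arrays over 0.9, which leaves 1 treated array. In these 2 fits Ccng1 had 0.68 and 0.58 and did not pass (adjusted p = 0.0619 and 0.212). The Ccng1 call ended when any 1 of 10 of the 23 arrays was left out (highest limma adjusted p 0.0838), while Cdkn1a, Phlda3, Dglucy and Aen passed in each of these fits. On the mean of all probe sets of a gene, the calls of Aen (0.23, adjusted p = 0.178) and Ccng1 (0.55, adjusted p = 0.112) ended.

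**Figure D2:**
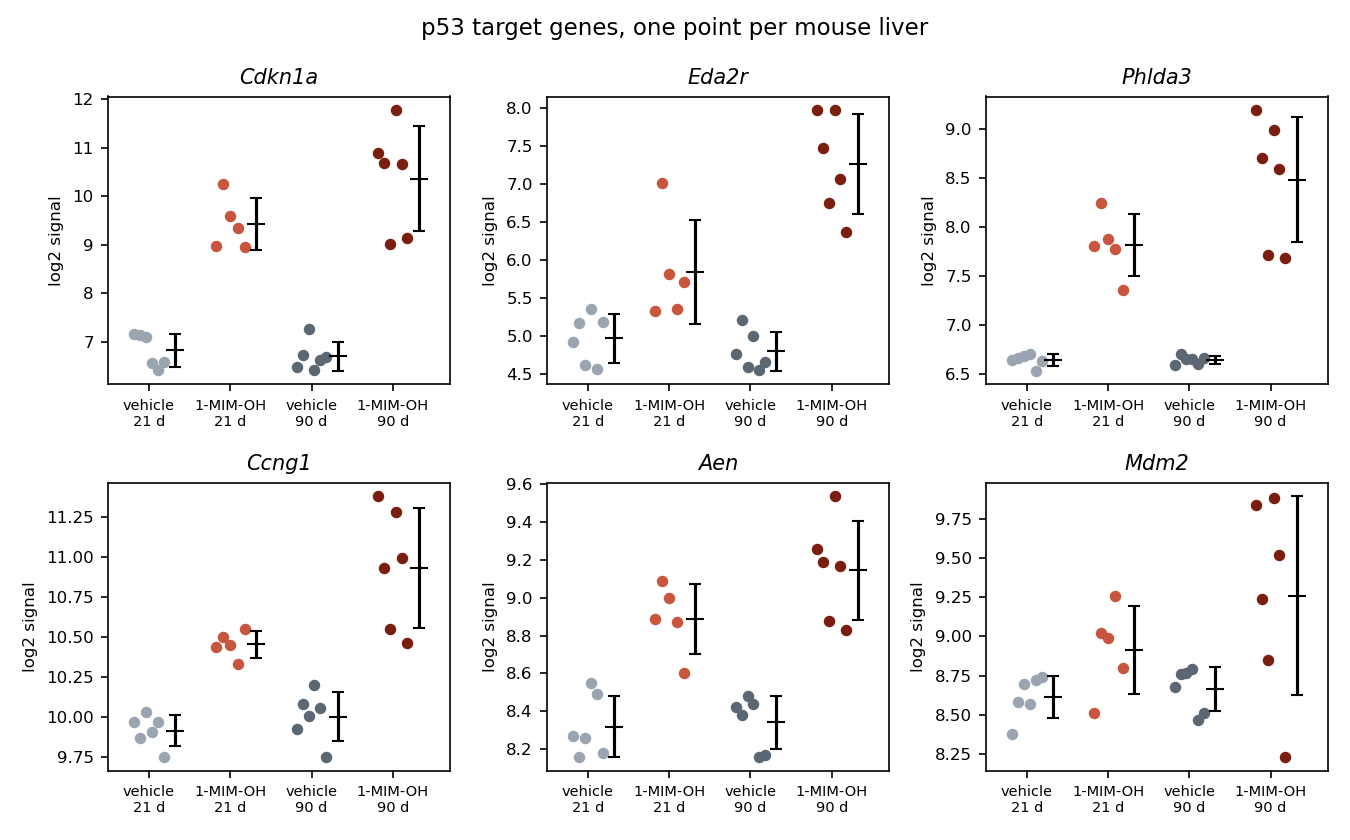
Log2 signal of 6 p53 target genes, 1 point per mouse liver, with the mean and SD of each group beside the points. Cdkn1a means were 6.83 and 9.43 in vehicle and treated livers at 21 d and 6.70 and 10.37 at 90 d, while Mdm2 did not pass the test at either time.

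DNA repair and antioxidant genes shifted upward in camera at 21 d, again next to the Gapdh difference of 0.67. Of 40 DNA repair genes, 0 passed over all genes tested; adjusted over the list alone, 4 were higher and 1 was lower. The median was 0.12 (camera adjusted p = 0.00764; adjusted p = 0.231 with an estimated correlation). Its largest values were those of Rev1, a translesion polymerase (0.55 ± 0.15 SE, limma adjusted p = 0.077), and Mgmt, which removes alkyl groups from guanine (0.32 ± 0.08 SE, adjusted p = 0.0545). Mgmt passed without treated 21 d replicate 2 or any 1 of 3 arrays at 90 d, treated replicates 1 and 6 and vehicle replicate 4 (adjusted p between 0.0379 and 0.0458). Of 31 genes of the NRF2 battery, which encode antioxidant and conjugating enzymes, 0 passed over all genes tested; adjusted over the list alone, 6 were higher and 3 lower. The median was 0.17 (camera adjusted p = 0.0241; adjusted p = 0.861 with an estimated correlation). Its largest values were those of the glutathione transferases Gsta2 (0.56 ± 0.27 SE, limma adjusted p = 0.301) and Gstm4 (0.49 ± 0.13 SE, adjusted p = 0.0584; passing without treated 21 d replicate 2 or treated 90 d replicates 1, 3 or 6, with adjusted p between 0.0217 and 0.0427). Neither list passed on genes with a mean of at least 6 (camera adjusted p = 0.0701 for DNA repair and 0.107 for NRF2). The NRF2 list did not pass on the mean of all probe sets (median 0.13, camera adjusted p = 0.059). The NRF2 call ended without treated 21 d replicate 2 (median 0.10, camera adjusted p = 0.0857), treated 21 d replicate 5 (0.14, adjusted p = 0.1) or vehicle 21 d replicate 5 (0.13, adjusted p = 0.0709).

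The other genes with the largest rises at 21 d were on none of the lists. Cplane1, a planar cell polarity effector of cilia, rose 3.06-fold (1.62 ± 0.26 SE on the log2 scale, limma adjusted p = 0.00522), although only 4 of its 7 probe sets had this sign. Cdhr5, a brush border cadherin, rose by 0.86 ± 0.14 (SE), and Endog, a mitochondrial endonuclease, by 0.71 ± 0.10 (SE). Increases between 1.57-fold and 1.80-fold were measured for 1810055G02Rik, the protease Tmprss2, the sphingosine phosphate transporter Spns2, the nucleoporin Aaas, Klhl25 and the noncoding Snhg14. Of these, 1810055G02Rik, Tmprss2, Aaas, Klhl25 and Snhg14 lost their calls when any 1 of 3, 6, 4, 10 and 8 arrays was left out, with highest limma adjusted p-values of 0.0638, 0.0808, 0.0616, 0.12 and 0.0878. The Klhl25 call also ended on the mean of all probe sets (0.37, adjusted p = 0.0803). The Gapdh difference of 0.67 stood beside these rises. When it was a covariate, Cdhr5, Spns2, Klhl25 and Snhg14 did not pass (adjusted p = 0.127, 0.219, 0.438 and 0.249). Their log2 fold changes were then 0.61 ± 0.16, 0.56 ± 0.16, 0.49 ± 0.19 and 0.64 ± 0.20 (SE), against 0.86 ± 0.14, 0.73 ± 0.14, 0.65 ± 0.15 and 0.65 ± 0.15 before. All 4 values shrank, that of Snhg14 only from 0.65 to 0.64, and all 4 standard errors grew. The lost calls thus do not show that these rises follow RNA integrity.

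Besides Fhit, 11 more genes were named for their falls at 21 d. Id1, an inhibitor of helix-loop-helix transcription factors, fell by 1.17 on the log2 scale (SE 0.25, limma adjusted p = 0.0286), and Abcd2, a peroxisomal fatty acid transporter on the list of female-biased genes, fell by 1.07 (SE 0.19, adjusted p = 0.0114). Ddah1, which degrades asymmetric dimethylarginine, fell by 0.87 (SE 0.11, adjusted p = 0.000968), and Cabcoco1 fell by 0.78 (SE 0.10, adjusted p = 0.000968). Cabcoco1 was dim, with mean log2 signals of 4.88 in vehicle and 4.10 in treated livers, under the array medians. Fras1, an extracellular matrix gene, fell by 0.98 (SE 0.17), and Wwox, an oxidoreductase gene at another common fragile site, fell by 0.79 (SE 0.16, adjusted p = 0.0247). Only 1 of 2 probe sets of Fras1 and 2 of 4 of Wwox had this sign. Gmds, Nubpl, Arhgap6, Tmtc2 and Pard3b had log2 fold changes between -0.98 and -0.78, and 1 of 2 probe sets of Tmtc2 and 2 of 3 of Pard3b had this sign. The Gmds signal was also dim, 5.31 in vehicle and 4.38 in treated livers. On the mean of all probe sets the calls of Wwox (-0.21, adjusted p = 0.133) and Tmtc2 (-0.37, adjusted p = 0.0537) ended. These falls stood next to the Gapdh 3' minus 5' difference of 0.67. When it was a covariate, Abcd2, Gmds and Nubpl did not pass (adjusted p = 0.157, 0.0688 and 0.114). Their log2 fold changes were then -0.90 ± 0.24, -0.84 ± 0.19 and -0.63 ± 0.16 (SE), against -1.07 ± 0.19, -0.94 ± 0.15 and -0.90 ± 0.14 before. Both smaller folds and larger standard errors thus entered the lost calls. The Pard3b call ended without treated 21 d replicate 3 (log2 fold change -0.73, adjusted p = 0.0535), and those of Id1, Arhgap6 and Wwox when any 1 of 6, 6 and 4 arrays was left out (highest adjusted p-values 0.0696, 0.0838 and 0.0638).

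Single members of other lists also passed at 21 d. Among rodent hepatocarcinogen markers other than p53 targets, 1 of 29 rose, the tubulin gene Tubb4b (0.50 ± 0.11 SE, limma adjusted p = 0.035), and adjusted over the list alone 3 were higher and 1 lower (camera adjusted p = 0.489). Gulo, the last enzyme of vitamin C synthesis and a pericentral marker, rose by 0.43 ± 0.08 (SE), and Hsd17b13, a lipid droplet protein and periportal marker, fell by 0.51 (SE 0.11). Sult1c2, a sulfotransferase, fell by 0.60 (SE 0.11, adjusted p = 0.0149), the only 1 of 16 genes on its list to pass, and Casp6, an executioner caspase, fell by 0.51 (SE 0.13, adjusted p = 0.0484). Sult1a1 itself had a log2 fold change of -0.22 ± 0.12 (SE, adjusted p = 0.377). Leaving out any 1 of 8, 5 and 19 arrays ended the calls of Tubb4b, Hsd17b13 and Casp6 (highest adjusted p-values 0.0983, 0.0882 and 0.125). On the mean of all probe sets the calls of Tubb4b (0.18, adjusted p = 0.101) and Casp6 (-0.23, adjusted p = 0.119) ended. Beside the Gapdh difference of 0.67, used as a covariate, Casp6 had -0.14 (adjusted p = 0.783), Gulo 0.28 (0.265), Tubb4b 0.61 (0.0669) and Hsd17b13 -0.51 (0.192), so these 4 calls ended. Casp6 had -0.08 without the 5 arrays over 0.9 (adjusted p = 0.918).

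The number of calls at 21 d rested on single arrays. It was 2265 without treated 21 d replicate 2, the only treated array of that group with a low Gapdh difference, 694 without treated 90 d replicate 1 and 905 without treated 90 d replicate 6. It was 146, 186 and 149 without treated 21 d replicates 1, 3 and 4, and 133, 159, 211, 174 and 162 without vehicle 21 d replicates 2 to 6. With the Gapdh difference as a covariate, 123 probe sets passed, 54 of them among the 431. Without the 5 arrays over 0.9, which leaves 1 treated array at 21 d that is assumed to vary like the other groups, 404 passed, 43 of them among the 431. Of the 31 passing genes named at 21 d, 12 passed in both of these fits, 11 passed in neither, and all 31 kept their direction; Cdkn1a, Phlda3 and Fras1 passed under every setting tried, as did Fhit and Cabcoco1 under each setting that kept their probe set.

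Camera called 13 lists with the Gapdh difference as a covariate at 21 d, in place of 3. Besides p53 targets, DNA repair and NRF2 genes, the higher lists were hepatocarcinogen markers (median 0.12, adjusted p = 0.0312), cell cycle genes (0.09, 0.00921), cholesterol synthesis (0.18, 0.00793), neutrophil markers (0.30, 0.000863), acute phase genes (0.20, 0.0152), interferon genes (0.31, 0.000819), oncofetal markers (0.20, 0.0312) and Kupffer cell markers (0.52, 0.00109). Bile acid genes (-0.11, adjusted p = 0.00793) and male-biased genes (-0.16, 0.000819) were lower. Without the 5 arrays over 0.9, which leaves 1 treated array, all 13 passed in the same directions, among them the hepatocarcinogen markers (0.36, adjusted p = 0.00973), and circadian genes, T and NK cell markers and cholangiocyte markers were added. That array, treated 21 d replicate 2, also stood apart in its acute phase score, 1.38 against -0.48 to -0.26 in the other 4 treated 21 d livers. Its Saa1 signal was 14.83, against 10.75 to 11.87. Vehicle 21 d livers also varied, with Saa1 signals from 11.17 to 14.12 and acute phase scores from -0.33 to 0.75. In the fit without the 5 arrays, the shifts of the acute phase and immune lists thus set 1 treated animal against these mixed vehicle livers.

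The second comparison asked the same after 40 treatments. Cdkn1a rose 12.7-fold, from 6.70 ± 0.31 (SD, n = 6) in vehicle to 10.37 ± 1.08 (SD, n = 6) in treated livers (log2 fold change 3.67 ± 0.34 SE, limma adjusted p = 2.13e-06). Eda2r, a receptor of the tumour necrosis factor family, rose 5.53-fold (2.47 ± 0.27 SE, adjusted p = 1.99e-05), and Phlda3 rose 3.58-fold (1.84 ± 0.19 SE, adjusted p = 1.18e-05). Fhit fell from 9.13 ± 0.22 (SD, n = 6) to 6.73 ± 1.05 (SD, n = 6), with a log2 fold change of -2.41 ± 0.32 (SE, adjusted p = 0.000301). For these 4 genes all 6 treated livers lay on 1 side of all 6 vehicle livers. In total 226 probe sets passed, 149 higher and 77 lower, or 91 higher and 45 lower genes; at an unadjusted p under 0.05 there were 4589 probe sets, against 2252 expected by chance.

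The p53 targets were again the list with the smallest camera p. Of 33 members 11 rose, 0 fell and 22 did not pass, and adjusted over the list alone 21 rose. Further members were Ddit4l, an inhibitor of mTOR signalling (1.15 ± 0.20 SE, limma adjusted p = 0.00691), Zmat3, an RNA-binding zinc finger protein (1.01 ± 0.16 SE), Ccng1 (0.93 ± 0.12 SE, adjusted p = 0.000207) and Aen (0.80 ± 0.11 SE, adjusted p = 0.000301). The median log2 fold change was 0.24 (camera adjusted p = 2.79e-19; adjusted p = 0.0185 with an estimated correlation), the only list to pass with an estimated correlation in any of the 4 contrasts. Mdm2 (0.60 ± 0.19 SE, adjusted p = 0.216) and Btg2 (0.74 ± 0.23 SE, adjusted p = 0.187) did not pass, although Mdm2 did without treated 90 d replicate 6 (0.80, adjusted p = 0.00706) and Btg2 did without treated 21 d replicate 2 (adjusted p = 0.0238). Btg2 also passed with the Gapdh difference as a covariate (0.77, adjusted p = 0.00773). Without the 5 arrays over 0.9 both did (adjusted p = 0.0055 for Mdm2 and 0.0018 for Btg2). In treated replicates 3 and 6 the Cdkn1a signal was 9.01 and 9.15, against 10.67 to 11.79 in the other treated livers.

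Outside the p53 list, the largest rises at 90 d were in genes of varied function. Cplane1 rose 8.24-fold (3.04 ± 0.25 SE, limma adjusted p = 1.97e-07), with 6 of 7 probe sets of this sign. Ddias, a suppressor of apoptosis after DNA damage, rose 3.54-fold (1.82 ± 0.29 SE), Cox6b2, a cytochrome c oxidase subunit of testis, rose 2.95-fold (1.56 ± 0.29 SE), and Bex1 rose 2.61-fold (1.39 ± 0.24 SE). Scara3, Tmem45a and Ppp1r14a, an inhibitor of myosin phosphatase, rose between 2.18-fold and 2.46-fold. The Tmem45a call ended without vehicle 90 d replicate 5 (adjusted p = 0.0511) and that of Ppp1r14a without treated 90 d replicate 2 or vehicle 90 d replicates 1 or 5 (highest adjusted p 0.0713).

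Among the genes that fell at 90 d, Tcf24, a helix-loop-helix factor, fell by 1.96 on the log2 scale (SE 0.25, limma adjusted p = 0.000207). The 2 genes at fragile sites fell again, Wwox by 1.13 (SE 0.16, adjusted p = 0.000515; 3 of 4 probe sets of this sign), as did Fras1 by 1.21 (SE 0.16; 1 of 2 probe sets of this sign). Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, fell by 1.15 (SE 0.18, adjusted p = 0.00274), and Steap2, a metalloreductase, by 0.95 (SE 0.15, adjusted p = 0.00198). Csad, which makes hypotaurine, the water channel Aqp4, the lysosomal nuclease Dnase2a, the synaptic scaffold Erc2, the autophagy gene Atg10 and the peptidase Trhde had log2 fold changes between -1.34 and -0.88. The calls of Aqp4, Csad and Atg10 ended when any 1 of 18, 4 and 10 arrays was left out (highest adjusted p-values 0.126, 0.0682 and 0.0802).

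**Figure D3:**
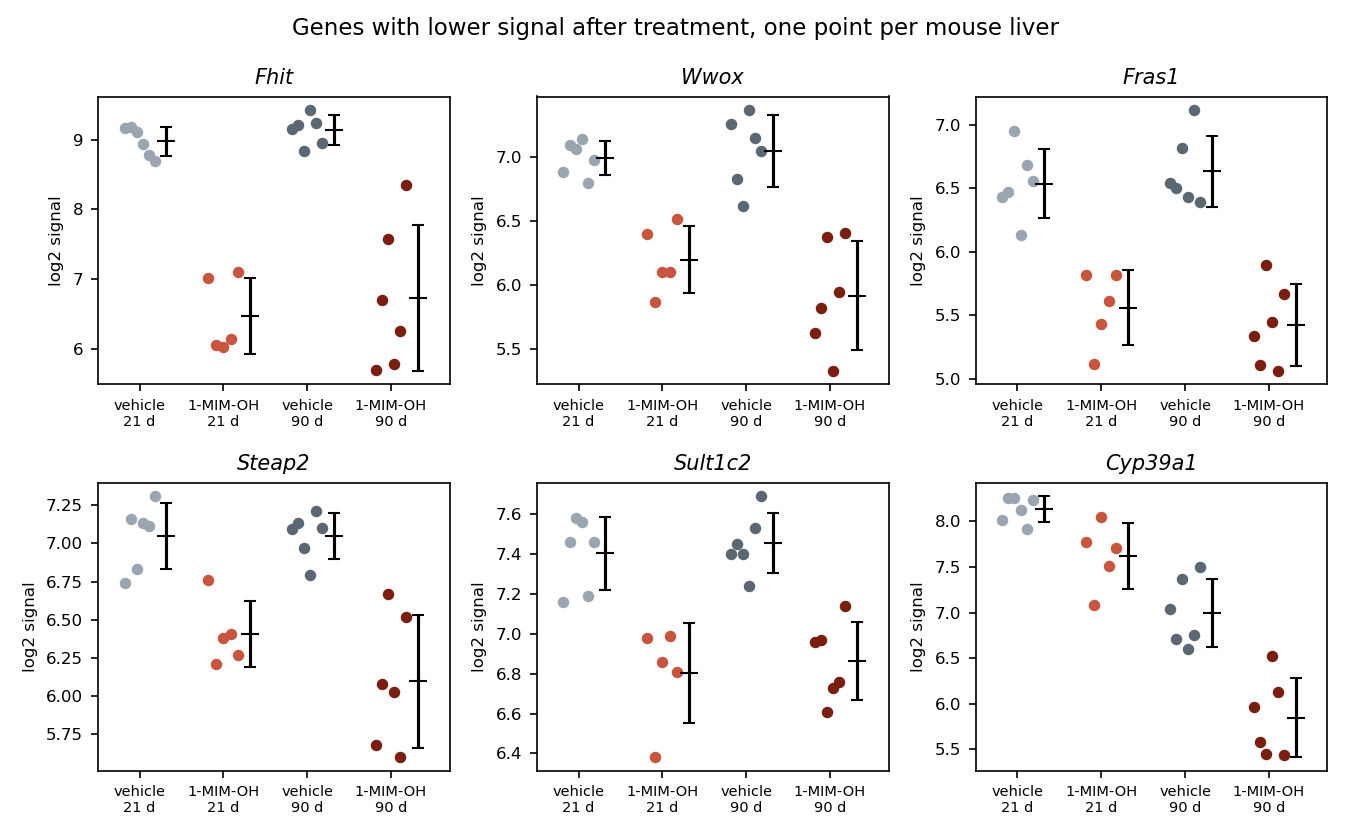
Log2 signal of 6 genes that passed as lower at 90 d, 1 point per mouse liver, with the mean and SD of each group beside the points. Fhit means were 8.98 and 6.47 in vehicle and treated livers at 21 d and 9.13 and 6.73 at 90 d, and Cyp39a1 was also lower in 90 d than in 21 d vehicle livers.

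The hepatocarcinogen marker, DNA repair, NRF2, cell cycle and oncofetal lists shifted upward in camera at 90 d, and none of them passed with an estimated correlation. Of 29 hepatocarcinogen markers 1 rose, Mgmt (0.50 ± 0.08 SE, limma adjusted p = 0.00196), and 7 were higher adjusted over the list alone (median 0.23, camera adjusted p = 0.00115; adjusted p = 0.132 with an estimated correlation). Of 40 DNA repair genes 2 rose, Mgmt and Rpa1, which binds single-stranded DNA (0.32 ± 0.07 SE, adjusted p = 0.0462), and 4 were higher adjusted over the list alone (median 0.05, camera adjusted p = 0.0474; adjusted p = 0.281 with an estimated correlation). The DNA repair list did not pass on the mean of all probe sets (median 0.02, camera adjusted p = 0.414) or without the 5 arrays with a Gapdh difference over 0.9 (0.04, adjusted p = 0.0981). Of 31 NRF2 genes 2 rose, Nqo1, a quinone reductase (0.63 ± 0.13 SE, adjusted p = 0.0241), and Srxn1, sulfiredoxin (0.45 ± 0.10 SE, adjusted p = 0.0363), and 13 were higher adjusted over the list alone (median 0.19, camera adjusted p = 2.62e-06; adjusted p = 0.18 with an estimated correlation). Of 34 cell cycle genes 0 passed and 5 were higher adjusted over the list alone (median 0.16, camera adjusted p = 3.33e-06; adjusted p = 0.18 with an estimated correlation); Mki67, a proliferation marker, had 0.55 ± 0.24 (SE, adjusted p = 0.426). Of 19 oncofetal and liver tumour markers 0 passed and 3 were higher adjusted over the list alone (median 0.19, camera adjusted p = 0.019; adjusted p = 0.461 with an estimated correlation). Afp (0.19 ± 0.12 SE, adjusted p = 0.612) and Gpc3 (-0.03 ± 0.09 SE, adjusted p = 0.944), fetal liver genes, did not pass. Leaving out any 1 of 18, 8 and 10 arrays ended the calls of Rpa1, Nqo1 and Srxn1 (highest adjusted p-values 0.142, 0.0764 and 0.111). Those of Rpa1 and Srxn1 ended on the mean of all probe sets (0.27 and 0.19, adjusted p = 0.0616 and 0.351). Leaving out any 1 of 8 arrays ended that of the DNA repair list (highest camera adjusted p 0.146). The oncofetal call ended without treated 90 d replicate 1 or 5 or vehicle 90 d replicate 5 (adjusted p = 0.0911, 0.106 and 0.0546), and on genes with a mean of at least 6 (adjusted p = 0.0787).

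Lists of immune genes and of other liver cells also shifted upward in camera at 90 d. Of 15 cholangiocyte and progenitor markers 1 rose, Anxa13, an annexin of epithelia (0.95 ± 0.17 SE, limma adjusted p = 0.00672), and 5 were higher adjusted over the list alone (median 0.16, camera adjusted p = 0.000493; adjusted p = 0.18 with an estimated correlation). Of 31 acute phase genes 1 rose, Serpina3n (0.55 ± 0.12 SE, adjusted p = 0.0408), and 2 were higher adjusted over the list alone (median 0.23, camera adjusted p = 0.0162; adjusted p = 0.678 with an estimated correlation). Of 31 interferon response genes and 21 Kupffer cell and macrophage markers 0 passed; adjusted over the list alone 1 and 2 were higher (medians 0.25 and 0.36, camera adjusted p = 0.00505 and 0.0232; adjusted p = 0.678 for both with an estimated correlation). The acute phase, interferon and Kupffer calls ended without treated 90 d replicate 3 (camera adjusted p = 0.596, 0.455 and 0.195). The acute phase call also ended without treated 90 d replicate 6 or vehicle 90 d replicates 1, 3 or 5 (highest adjusted p of these 0.139), and the Kupffer call without treated 90 d replicates 5 or 6 or those same vehicle arrays (highest of these 0.117). On genes with a mean of at least 6, the cholangiocyte (median 0.16, camera adjusted p = 0.159), Kupffer (0.36, 0.139) and acute phase lists (0.33, 0.0774) did not pass. Serpina3n lost its call when any 1 of 13 arrays was left out (highest limma adjusted p 0.111).

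Metabolic and hepatocyte lists shifted downward in camera at 90 d, with few members passing singly. The median log2 fold changes were -0.09 for 15 genes of glucose metabolism (camera adjusted p = 0.0134), -0.09 for 16 male-biased genes (0.0162), -0.12 for 24 genes of the unfolded protein and amino acid stress response (0.00505) and -0.03 for 18 hepatocyte markers (0.0474). With an estimated correlation the adjusted p-values were 0.18, 0.461, 0.461 and 0.461. Of these 4 lists, 1 gene passed, Cyp2u1, a fatty acid hydroxylase (-0.65 ± 0.14 SE, limma adjusted p = 0.0408). Adjusted over the list alone, 1 male-biased gene was higher and 2 were lower, and 0 genes of the other 3 lists passed. The glucose list lost its call without treated 90 d replicate 3 (camera adjusted p = 0.0669), the male-biased and unfolded protein lists without treated 90 d replicate 1 (0.0911 and 0.0806), and the hepatocyte list when any 1 of 9 arrays was left out (highest 0.195), on genes with a mean of at least 6 (0.0918) and with the replicate number as a block (0.054). Leaving out any 1 of 15 arrays ended the Cyp2u1 call (highest limma adjusted p 0.101).

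**Figure D4:**
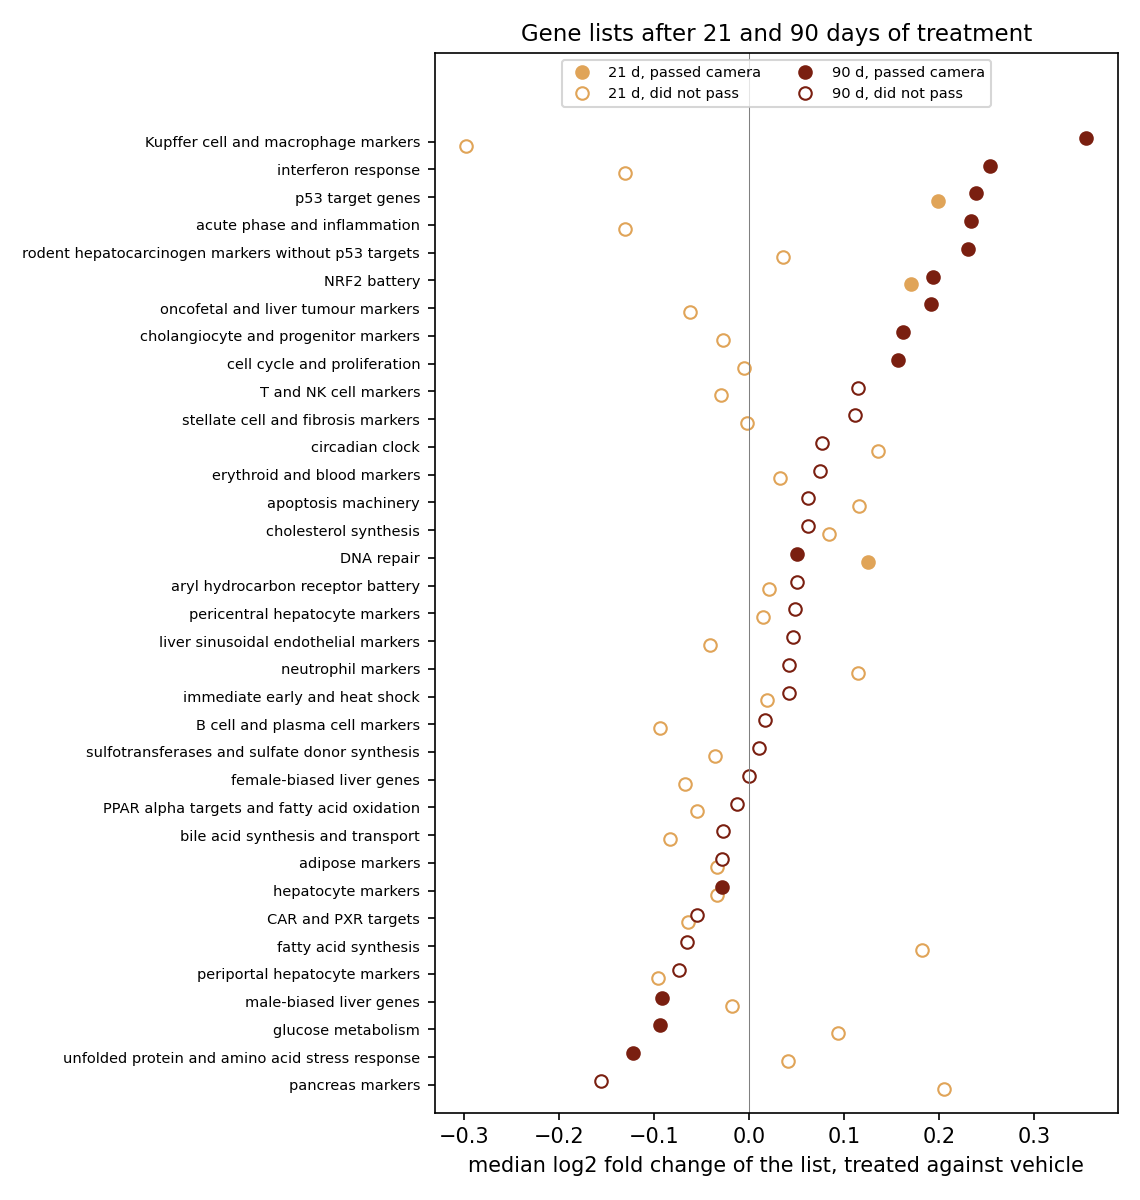
Median log2 fold change, treated against vehicle, of the 35 gene lists at 21 and 90 d; filled points passed camera at an adjusted p under 0.05 and open points did not. The p53 targets had medians of 0.20 and 0.24, and 3 lists passed at 21 d against 14 at 90 d with the preset correlation. With an estimated correlation 0 and 1 passed.

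Among the remaining lists, those of aryl hydrocarbon receptor, circadian, bile acid and sulfotransferase genes each held 1 passing gene at 90 d: Nqo1, the clock repressor Cry1 (-0.52 ± 0.12 SE, limma adjusted p = 0.0462; call lost when any 1 of 17 arrays was left out, highest adjusted p 0.139), Cyp39a1 and Sult1c2 (-0.59 ± 0.11 SE, adjusted p = 0.00917). The aryl hydrocarbon receptor targets Cyp1a1 and Cyp1a2 had log2 fold changes of 0.22 ± 0.12 and -0.04 ± 0.13 (SE, adjusted p = 0.569 and 0.952) at 90 d, and of -0.09 ± 0.13 and 0.17 ± 0.13 (SE, adjusted p = 0.811 and 0.585) at 21 d. Ephx1, microsomal epoxide hydrolase, had 0.44 ± 0.13 at 21 d (SE, adjusted p = 0.0797) and 0.45 ± 0.12 at 90 d (SE, adjusted p = 0.0991). Without treated 90 d replicate 3 Ephx1 passed at both times (adjusted p = 0.0484 and 0.0148), without treated 90 d replicate 6 it passed at 90 d (0.0354), and without treated 21 d replicate 2 Cyp1a2 passed at 21 d (0.37, adjusted p = 0.0182). Sult1a1 had 0.00 ± 0.11 at 90 d (SE, adjusted p = 0.997).

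With all arrays and no covariate, the aryl hydrocarbon receptor, circadian, bile acid and sulfotransferase lists did not pass camera at either time. The same held for targets of CAR and PXR and of PPAR alpha, apoptosis, cholesterol synthesis, fatty acid synthesis, female-biased genes, immediate early and heat shock genes, pericentral and periportal markers, and markers of T and NK cells, B cells, neutrophils, sinusoidal endothelium, stellate cells, blood, pancreas and adipose tissue. Over these 21 lists the camera adjusted p lay between 0.0601 and 0.968 at 21 d and between 0.0782 and 0.980 at 90 d. Some passed when 1 array was left out: without treated 21 d replicate 2, the circadian and fatty acid synthesis lists at 21 d (camera adjusted p = 0.0023 and 0.00541), and at 90 d the pancreas list without treated 90 d replicate 5 (0.000474) and the stellate cell list without vehicle 90 d replicate 3 (0.00358) or treated 90 d replicate 3 (0.0118). Others did so with camera adjusted p between 0.0108 and 0.0492: CAR and PXR targets at 21 d without vehicle 21 d replicate 1, periportal markers at 21 d without treated 21 d replicate 4, PPAR alpha targets at 90 d without treated 90 d replicate 4, and bile acid genes at 90 d without treated 90 d replicate 2. In the same range were periportal markers at 90 d without treated 90 d replicates 2 or 4 or vehicle 90 d replicate 4, and pancreas markers at 90 d without vehicle 90 d replicates 3 or 5. So was fatty acid synthesis, at 21 d without vehicle 21 d replicates 1, 4 or 6 or treated 90 d replicate 2, and at 90 d without treated 90 d replicates 2, 4 or 6. Acute phase, interferon and Kupffer lists, which passed only at 90 d, shifted downward at 21 d without treated 21 d replicate 2 (medians -0.34, -0.36 and -0.84; camera adjusted p = 0.00166, 0.0387 and 0.00108). The vehicle 21 d livers in that comparison included some with high acute phase scores, up to 0.75. The median, the mean and the camera direction did not share a sign for glucose metabolism, male-biased genes, immediate early genes, cell cycle genes, cholangiocyte markers and stellate cell markers at 21 d, and for cholesterol synthesis, circadian, female-biased, sulfotransferase and B cell genes at 90 d.

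The count of calls at 90 d was 389 without treated 90 d replicate 6 and 376 without treated 21 d replicate 2. It was 119, 340, 134 and 141 without treated 90 d replicates 2 to 5, and 131, 140, 147, 114 and 143 without vehicle 90 d replicates 1, 3, 4, 5 and 6. With the Gapdh difference as a covariate 504 probe sets passed and without the 5 arrays over 0.9 761 passed, and these included 226 and 221 of the 226. All 35 passing genes named at 90 d passed in both fits. Over all settings tried, stricter thresholds included, 19 of the 35 kept their calls. In fits on only the 2 groups compared 24 did, and with no moderation of the variance 25 did. The calls of Cox6b2, Dnase2a, Trhde, Anxa13 and Mgmt held when any 1 array was left out, but not under every setting. All 14 lists called at 90 d passed with the covariate, and 11 did without the 5 arrays, where DNA repair, acute phase genes and hepatocyte markers did not (camera adjusted p = 0.0981, 0.126 and 0.0823).

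The 2 effects were then set against each other. Over 18193 genes, the log2 fold changes at 21 and 90 d had a Pearson correlation of 0.269 and a Spearman correlation of 0.207; this is across genes, which are not independent replicates, and the 2 effects share no control arrays. The Pearson value was 0.045 without treated 21 d replicate 2. Of the genes that passed, 16 were higher at both times and 21 lower at both, against 0.525 and 0.267 expected for independent lists, and 0 passed in opposite directions. Of the 213 genes passing at 21 d, 200 had the same sign at 90 d, and of the 136 passing at 90 d, 133 had the same sign at 21 d; over all 18193 genes the share with the same sign was 55.8%. For Cdkn1a the effect was larger at 90 d by 1.07 ± 0.49 (SE, limma adjusted p = 0.509), for Eda2r by 1.59 ± 0.39 (adjusted p = 0.492) and for Cplane1 by 1.43 ± 0.36 (adjusted p = 0.492). The Eda2r difference passed without treated 21 d replicate 2 (1.88, adjusted p = 0.0333). Id1 fell at 21 d and had -0.08 ± 0.24 at 90 d, and this difference of 1.09 ± 0.35 did not pass (SE, adjusted p = 0.492).

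**Figure D5:**
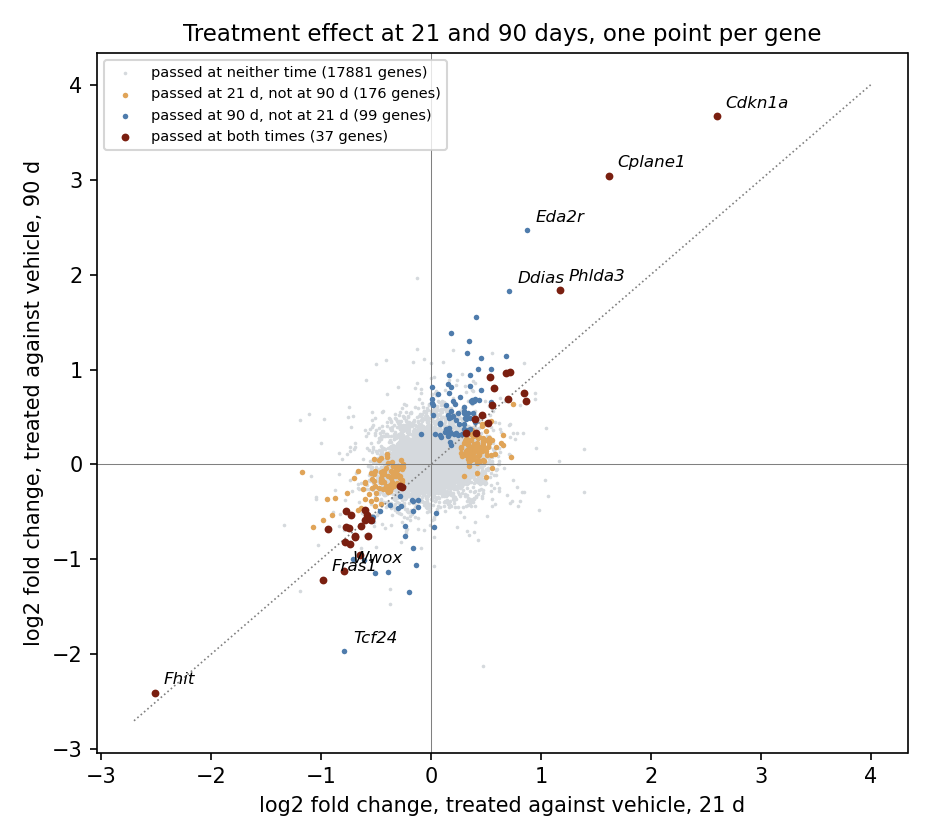
Log2 fold change, treated against vehicle, at 21 d (horizontal) and at 90 d (vertical), 1 point per gene for 18193 genes, coloured by the time at which the gene passed; the dotted line marks equal effects. The 37 genes that passed at both times lie in the quadrants of equal sign, with Cdkn1a at 2.60 and 3.67 and Fhit at -2.51 and -2.41.

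No probe set passed limma's test of the difference between the effects (0 of 45037; smallest adjusted p 0.492), while 4320 had an unadjusted p under 0.05, against 2252 expected by chance. With all arrays, the count was also 0 under other scalings, filters, variance models and array weights, and with the Gapdh difference as a covariate. It was 53 without treated 21 d replicate 2 and 6 without the 5 arrays with a Gapdh difference over 0.9. Camera called 10 lists for this difference. The p53 targets (median difference 0.23), cell cycle genes (0.18), acute phase genes (0.30), interferon genes (0.42), Kupffer cell markers (0.74), oncofetal markers (0.14) and cholangiocyte markers (0.28) shifted upward from 21 to 90 d, and fatty acid synthesis (-0.10), male-biased genes (-0.14) and the unfolded protein response (-0.14) downward. Camera adjusted p-values lay between 0.0025 and 0.0137, and adjusted p-values with an estimated correlation were 0.654 or 0.848. Adjusted over the list alone, 2 p53 targets and 3 cholangiocyte markers were higher and 0 genes of the other lists passed; the Gapdh difference between treated and vehicle livers was 0.67 at 21 d and 0.03 at 90 d. With the Gapdh difference as a covariate, the median difference was -0.07 for the Kupffer list and 0.06 for the male-biased list, and the camera direction also turned for the acute phase and interferon lists (0.02 and 0.03). The difference of the p53 targets did not pass with the covariate, with a median of 0.07 in place of 0.23 (camera adjusted p = 0.3), nor did those of cell cycle genes (0.12, adjusted p = 0.24), fatty acid synthesis (-0.05, 0.277), oncofetal markers (0.02, 0.936) and cholangiocyte markers (0.10, 0.117). Of the 10 lists, the unfolded protein response alone kept its call. Without the 5 arrays over 0.9, none of the 10 kept its call in the same direction, with 0.10 for p53 targets (adjusted p = 0.57) and 0.04 for cholangiocyte markers (0.956).

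Several list calls for the difference of the effects ended without single arrays. The Kupffer call ended without treated 21 d replicate 1 or 3, vehicle 21 d replicate 1 or treated 90 d replicate 5 or 6 (highest camera adjusted p 0.152). The interferon call ended without vehicle 21 d replicate 1 (0.158) or treated 90 d replicate 3 (0.167), and the acute phase call without treated 90 d replicate 3 (0.16) or 6 (0.0554). The male-biased call ended without treated 21 d replicate 4, vehicle 21 d replicate 4 or treated 90 d replicate 1 (highest 0.0651), and the oncofetal call without treated 21 d replicate 3 or treated 90 d replicate 5 (highest 0.0715). The calls of p53 targets, cell cycle genes, fatty acid synthesis, the unfolded protein response and cholangiocyte markers held when 1 array was left out at a time, but on genes with a mean of at least 6 the cholangiocyte call ended (median 0.04, camera adjusted p = 0.547), as did the male-biased call (-0.14, adjusted p = 0.0837). Of these 5 calls, only that of the unfolded protein response held with the Gapdh difference as a covariate.

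Vehicle livers at 90 d and at 21 d, which differ in the animals' age as well as in the length of dosing, differed in 3 probe sets, 1 higher without a gene name and 2 lower. Cyp39a1 fell by 1.14 (SE 0.18, limma adjusted p = 0.0326) and Tceal8 by 0.93 on the log2 scale. At an unadjusted p under 0.05 there were 2686 probe sets, against 2252 expected. Camera called 6 lists. Pancreas markers (median 0.47, adjusted p = 0.000802), fatty acid synthesis (0.07, 0.0374) and the unfolded protein response (0.11, 0.0374) were higher at 90 d. Acute phase genes (-0.20, adjusted p = 0.0139), Kupffer cell markers (-0.33, 0.0207) and interferon genes (-0.20, 0.0374) were lower. The adjusted p was 0.967 for all 6 with an estimated correlation, and adjusted over the list alone only fatty acid synthesis held passing genes, 1 higher and 1 lower. The count of probe sets was 16 without treated 21 d replicate 2, 6, 7 and 5 without treated 21 d replicates 1, 3 and 4, and 8, 5, 5 and 9 without treated 90 d replicates 2, 3, 4 and 6. It was 5 without vehicle 21 d replicate 4 or vehicle 90 d replicate 6, 1 without vehicle 90 d replicate 4, and 0 without vehicle 21 d replicate 1 or 5 or vehicle 90 d replicate 1 or 5. The Cyp39a1 and Tceal8 calls ended when any 1 of 11 and 4 arrays was left out (highest adjusted p-values 0.161 and 0.072). The pancreas call ended without vehicle 90 d replicate 1 (camera adjusted p = 0.0533) and, like that of fatty acid synthesis, on genes with a mean of at least 6 (0.0545 and 0.163). The interferon call ended with the replicate number as a block and on the mean of all probe sets (0.0721 and 0.0758). The other 5 calls each ended without several vehicle arrays; for acute phase, interferon and Kupffer lists the highest adjusted p-values were 0.19, 0.922 and 0.519 without vehicle 21 d replicate 1, for fatty acid synthesis 0.163 without vehicle 90 d replicate 1, and for the unfolded protein response 0.217 without vehicle 90 d replicate 2.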

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

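The tests of the 3' minus 5' differences were chosen only after the results were seen; the search for single distant arrays was set beforehand. The search covered 144 groups of values, those of the genes with the largest changes, of the genes named whatever their result and of the Gapdh difference. In 5 of them, 1 array was set apart, where about 7.2, or 1 in 20 groups, would be by chance. Cdkn1a was 7.27 in vehicle 90 d replicate 3 (others 6.41 to 6.72), Cyp1a1 was 6.5 in treated 21 d replicate 1 (others 5.73 to 5.94), and Btg2 was 7.96 in vehicle 90 d replicate 2 (others 7.35 to 7.56). In treated 21 d replicate 2, Cyp1a2 was 12.59 (others 13.45 to 13.69) and Mki67 was 6.59 (others 5.05 to 5.4). That array is also the 1 treated array at 21 d with a low Gapdh 3' minus 5' difference.

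The treatment effect differed between 90 and 21 d for 10 lists in camera with the preset correlation, and for 0 with an estimated correlation. The median differences were 0.23 for p53 targets, 0.18 for cell cycle genes, -0.10 for fatty acid synthesis, -0.14 for male-biased genes, 0.30 for acute phase genes, 0.42 for interferon genes, -0.14 for the unfolded protein response, 0.14 for oncofetal markers, 0.74 for Kupffer cell markers and 0.28 for cholangiocyte markers. In treated livers at 21 d, the Gapdh and beta-actin 3' minus 5' differences exceeded those of vehicle livers by 0.67 and 0.58.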

How the results depend on the processing

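The 2 settings that use the Gapdh 3' minus 5' difference were tests chosen only after the results were seen. The counts of passing probe sets are given for 21 d, 90 d and the vehicle groups, where 431, 226 and 3 passed. The cause of each shift in a count was not tested. Keeping probe sets above the median probe set gave 729 at 21 d; keeping those with a mean of at least 6 gave 813 at 21 d and 6 between the vehicle groups. Fits on only the 2 groups compared gave 207, 149 and 20. Array weights gave 1426, 463 and 32. No moderation of the variance gave 247 and 150, and an intensity trend with a robust prior gave 7 between the vehicle groups. By construction, stricter thresholds gave fewer: 121 and 110 with at least 1.5-fold, and 34, 81 and 0 at an adjusted p under 0.01. The replicate number as a block gave 91, 148 and 0. Replicate numbers were taken as names, and whether animals with the same number were handled together is not known. Each group's mean was subtracted from probe sets with a mean of at least 6. Between animals with the same number, the remaining values had correlations between -0.46 and 0.46, with 5 of 33 pairs over 0.1. Quantile normalisation gave 6 and centring 8 between the vehicle groups.

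Of the 35 lists, camera called 3, 14, 10 and 6 at 21 d, at 90 d, for the difference and between the vehicle groups. With an estimated correlation it called 0, 1, 0 and 0. Fry called 2, 6, 0 and 0 for movement in 1 direction and 9, 11, 0 and 0 for change in either direction. On genes with a mean of at least 6, camera called 1 at 21 d and 9 at 90 d.

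With the Gapdh difference as a covariate, 123 probe sets passed at 21 d and 504 at 90 d; camera called 13 lists at 21 d, 3 for the difference and 2 between the vehicle groups. The camera direction of some lists turned, though not always the sign of the median. Before the covariate, the male-biased median at 21 d was already -0.02. The medians of acute phase and interferon genes for the difference were 0.30 and 0.42 before, and they stayed positive. At 21 d the medians became -0.16 for male-biased genes, 0.20 for acute phase genes, 0.31 for interferon genes, 0.20 for oncofetal markers and 0.52 for Kupffer cell markers. For the difference of the effects they became 0.0604 for male-biased genes, 0.0175 for acute phase genes, 0.0251 for interferon genes and -0.0719 for Kupffer cell markers.

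Without the 5 arrays with a Gapdh difference over 0.9, 761 probe sets passed at 90 d, 6 for the difference and 18 between the vehicle groups; camera called 16 lists at 21 d, and the correlation of the effects was 0.521. At 21 d the medians became -0.44 for circadian genes, -0.21 for male-biased genes, 0.66 for acute phase genes, 0.57 for interferon genes, 0.31 for oncofetal markers, 1.52 for Kupffer cell markers and 0.22 for T and NK cell markers. For the difference they became 0.73, 0.15, -0.37, -0.23, -0.0787, -1.28 and -0.14 in the same order. The 21 d values rest on 1 treated array.

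Leaving out 1 array at a time, the count ran from 133 to 2265 at 21 d, from 114 to 389 at 90 d, from 0 to 53 for the difference and from 0 to 16 between the vehicle groups. The lists called ran from 2 to 7, 9 to 16, 8 to 13 and 0 to 7. The correlation of the effects ran from 0.045 to 0.357.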

Other observations

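The genes and tests in this part were chosen only after the results were seen. Beyond the genes named by rule, Polk, a translesion DNA polymerase on the p53 list, passed at both times, higher by 0.56 ± 0.12 and 0.62 ± 0.12 (SE, log2 scale, limma adjusted p = 0.03 and 0.00978). Eif2d, a translation factor, was higher by 0.47 ± 0.09 and 0.53 ± 0.09 (SE). Smyd3, a lysine methyltransferase, had log2 fold changes of -0.74 ± 0.10 and -0.67 ± 0.09 (SE, adjusted p = 0.000968 and 0.000497), Ncam2, a cell adhesion gene, of -0.77 ± 0.13 and -0.66 ± 0.13, and Pik3c2g, a phosphoinositide kinase of liver, of -0.69 ± 0.15 and -0.77 ± 0.14. Of the 136 genes passing at 90 d, 120 had the larger effect at 90 d, a share raised by selecting them at 90 d.

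Genes that passed as lower were more often long: of those lower at 21 and 90 d, 26 of 108 and 21 of 45 spanned over 200 kb, against 901 of all 18032 genes with a span, and 2 of 105 and 6 of 91 of the higher genes did. A score of long against short genes was lower in treated livers by 0.099 at 90 d (exact permutation p = 0.00649) and by 0.079 at 21 d (exact permutation p = 0.0519). Genomic span had a correlation of -0.0281 with the log2 fold change at 21 d, where the median effect was -0.09 over 500 kb. This does not decide on an effect graded by span at 21 d. The score rose with the Gapdh difference among treated 90 d livers, and that difference was 0.67 higher in treated than in vehicle livers at 21 d. The 1 treated 21 d array under the Gapdh limit had a score 0.172 below the vehicle mean. At 90 d such an effect is not argued against, as the correlation was -0.0964 and the median effect fell from 0.04 under 5 kb to -0.05 over 500 kb. RNA integrity at 90 d is argued against because the score rose with the Gapdh difference among treated 90 d livers (r = 0.883, permutation p = 0.0215, n = 6). Within the 2 vehicle groups this r was only 0.315 (permutation p = 0.325, n = 12). Within all groups but treated 21 d it was 0.600 (permutation p = 0.0130, n = 18). The score difference at 90 d was also still -0.114 without the array over the Gapdh limit, which had the highest score of its group. Among genes with a mean of at least 8 the correlation at 90 d was -0.129, so it did not shrink in brighter genes. Their medians were 0.06 under 5 kb, -0.008 from 200 to 500 kb and -0.15 over 500 kb (28 genes). Of the 16 lower genes of this brightness 2 spanned over 200 kb, against 173 of all 6180, which is too few to exclude dim probe sets. Between the vehicle groups, 90 against 21 d, the correlation was -0.0649, so a weak correlation of this sign also arose without the compound. Treated and vehicle livers were compared on the same day, so time is matched in their contrasts. The vehicle comparison cannot test handling that differed between treated and vehicle livers. Why these long genes were lower stays open.

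More probe sets passed at 21 d than at 90 d, 431 against 226. RNA integrity is a candidate explanation: for the 176 genes passing only at 21 d, the median slope on the Gapdh difference within the 90 d groups, signed by the 21 d change, was 0.241. In 10000 random lists the median was 0.112 and the 95th percentile 0.149. These lists were matched on mean expression, not on the size of the 21 d change or on spread. Genes chosen for large changes may exceed them for other reasons, so this does not decide. The slope also leans on treated 90 d replicate 6, with a Gapdh difference of 1.24 against a group mean of 0.53. The spread within treated livers at 90 d was 1.03 times that at 21 d, which leaves open whether a larger spread took part. The order turned with the Gapdh difference as a covariate (123 and 504), without treated 21 d replicates 1 (146 and 209) or 4 (149 and 207) or vehicle 21 d replicates 2 (133 and 178), 3 (159 and 170) or 6 (162 and 181), with the replicate number as a block (91 and 148) and at an adjusted p under 0.01 (34 and 81). Treatment and the Gapdh difference run together at 21 d, so what part of the 431 follows the compound stays open, as does whether more genes changed at 21 d at all.

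In 2 treated 90 d livers, replicates 3 and 6, p53 targets rose less than in the other 4. An exchange with 21 d livers is argued against by the time score, 0.113 in the lower of the 2, while all treated 21 d livers lay below 0. The same 2 livers had the highest acute phase scores of their group (1.19 and 0.683), whereas at 21 d the liver with the highest acute phase score, replicate 2 (1.38), had the highest p53 score. Over the 11 treated livers the correlation of the 2 scores was -0.188 (permutation p = 0.581) and the Spearman value was -0.364 (permutation p = 0.322). The correlation was -0.705 without the 2 livers farthest out in acute phase score, treated 21 d replicate 2 and treated 90 d replicate 3. Replicate 3 is 1 of the 2 livers at issue, so the value of -0.705 does not bear on it. Replicate 6, with the lowest p53 score of its group (0.070), was also the 1 treated 90 d array over the Gapdh limit (1.24). Replicate 3 had a Gapdh difference of 0.21. At 21 d, replicate 2 was the only treated array with a low Gapdh difference (0.14). An acute phase state of the animal may be involved and stays open, as does RNA integrity. For this pattern, RNA integrity and differences in uptake or dose were not tested.

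The role of chance in grouping the animals was examined with 100 splits of the arrays per contrast, the real one included. At 90 d, 1 split, the real one, gave as many as 226, and the highest other gave 1. This makes chance unlikely at 90 d, but not every possible split was drawn, so chance is not excluded. At 21 d, 2 splits gave at least 431; the highest other, 546, put the 4 treated arrays with a high Gapdh difference together with vehicle replicate 3. Its 2 sides differed by 0.76 in the Gapdh difference and by -0.776 in the acute phase score, so RNA integrity, acute phase state and treatment are not separated in it. Between the vehicle groups 2 splits gave at least 3, and the highest other gave 4. For the difference of the effects the real count was 0, which all 100 splits reach by construction, so this comparison says nothing about chance; the highest other gave 970.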
